A study of Arabidopsis thaliana with 48 samples.

How the data were processed

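RNA of Arabidopsis thaliana was measured on 48 oligonucleotide arrays, each hybridised with 2 RNAs, 1 labelled with Cy3 and 1 with Cy5. The labels name established autotetraploid lines of the accessions Col-0 and Ler-0 and their diploid parents. The samples formed 8 groups of 4, 8 or 12 arrays. In the diploid Ler-0 vs Col-0 group the 4 arrays held 2 biological replicates, each hybridised with both dye orientations, and the dye swaps were averaged before the fit. Per the labels, each seedling sample outside the second Ler-0 set pooled 100 seedlings, and the leaf samples were taken from the sixth to eighth leaves.

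Per the file headers, the authors extracted each scanned array with Agilent Feature Extraction, in version 9.1.1.1, 9.5.1.1 or 9.5.3.1, and these files give spot signal and local background as intensity. Per the file headers, the log ratio in these files is a log10 of Cy5 over Cy3 after background subtraction and dye normalization by the extraction software. Per the file headers, the other columns used are quality marks of the deposited extraction, such as outlier, saturated and well above background, and the control type. The authors deposited a table of log2 ratios, which per the labels were normalized with limma. The version and the background and normalization steps are not given in the sources used here. The median of a column of that value table lay between -0.02 and 0.042. The Pearson correlation of a column across spots, which are not independent replicates, was 0.796 to 0.992 with the Agilent log ratio and 0.877 to 0.998 with the ratios computed here.

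The ratios used here were computed from the mean signal and the median background of each spot. With limma 3.58.1 in R 4.3.3, background was corrected by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess with a span of 0.3. Each file held 39102 features, of which 37685 were not controls. Spots marked as outliers by the extraction software were left out, and the spots of a probe were averaged, which gave 37478 probes. Of these, 26236 carried a locus name and stood for 25665 loci. For the 541 loci with several probes the probe with the highest mean signal over all arrays was used. The build on which the probes were designed is not given in the sources used here, so no coordinates are printed. Gene symbols and the order of genes came from the reference tables of assembly TAIR10.1, which held 25449 of the loci and not the other 216, and 10189 loci had a symbol. The 11242 probes without a locus name were kept apart.

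A gene was tested in a comparison when its probe was marked well above background on at least 0.5 of the arrays of the comparison in the channel of at least 1 of the RNAs. The extraction software used a multiplier of 2.6 for this mark in version 9.1.1.1 and of 13 in the later versions, so detection was stricter on the arrays read with the later versions. The 46 resulting ratios per gene were fitted in 1 limma model with a coefficient for each group, turned by the dye orientation, and a dye term for each gene. Only the Col-0 seedling arrays held both orientations outside the diploid swaps, so the dye term rested on them. In those arrays the orientation coincided with the slide, the scanner and the software version. Values were missing in 12.1% of genes, which were fitted on the remaining arrays, and the prior degrees of freedom of the moderated variance were 2.11. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. Differences between groups were tested as contrasts of the same fit. Because of the dye term, the contrast of Ler-0 with Col-0 seedlings and that of leaves with seedlings were equal to the arrays of the one group minus the 4 Col-0 seedling arrays of the same orientation. The main model, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

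Each slide carried 4 arrays, and 5 of the groups lay on 1 slide each, so that slide and group could not be separated there by design. Beside the counts of genes, and some of the named genes, the result with the slide as a random block is given. With this block 32 list shifts passed at the preset correlation. The correlation within slides, estimated with statmod 1.5.0 from 5000 genes, was 0.357, and for groups on 1 slide this block assumes that slides vary alike in all groups.

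The genes named in the text followed 4 parts of a rule. In each comparison they were the 8 genes with a symbol that had the largest rise and the 8 with the largest fall among those past the threshold with the same direction on every array, or on all but 1 in groups of 8 or 12 arrays. From each gene list with a member past the threshold, up to 3 members with the largest change were taken, of which some are left out here for length, and a few results are left out because they were withheld. In comparisons of the accessions all members of the list of known differences were named. For differences between groups the 5 largest in each direction were named. Fold changes are given as bounds where 1 of the RNAs was not well above background, and not at all where a channel was saturated on all arrays of the comparison.

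The gene lists, matched by locus, covered the cell cycle, endoreduplication and CDK inhibitors, the DNA damage response, DNA methylation and silencing, salicylic acid defence, jasmonate and wounding, ethylene, cold with drought and abscisic acid, heat shock, oxidative stress, cell wall and expansion, photosynthesis, seed storage and maturation, root markers, senescence, epidermis and trichomes, floral organ identity, flowering time, the circadian clock, flavonoids and anthocyanins, glucosinolates, auxin, iron homeostasis, and known differences between Col-0 and Ler-0. Shifts of lists against all other genes were tested with camera of limma at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over all lists and comparisons. At the preset correlation 30 shifts passed, and 1 passed with the estimated correlation.

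Medians of lists were also taken under median centring, the Agilent log ratio and the value table, which with loess are the scalings named in the text. The chromosome shift of an array was the median log2 ratio of the genes of a chromosome minus that of the other chromosomes, and a shift of at least 0.1 was counted. Neighbouring called genes were counted against 10000 random draws of as many tested genes. Correlations or covariances between comparisons were set beside those of 20 simulated sets of unchanged groups, since comparisons that share a dye term correlate without any change. The numbering of replicates was checked as a possible pairing of arrays between groups. Ratios of arrays with the same replicate number correlated across genes at -0.28 to 0.07 between Ler-0 and Col-0 seedlings, at -0.07 to 0.11 between leaves and seedlings of Col-0 and at -0.09 to 0.25 between the second Ler-0 set and the leaves, so replicate numbers were not used as pairs. The pipeline was tested on simulated data, in which changes of 2-fold were recovered for 71.6% to 98.5% of altered genes, according to the comparison, and 0% to 9.6% of the calls were false. The simulated arrays varied independently, without the correlation of 0.357 within slides. These shares therefore do not cover calls that arise because arrays of a slide or line are alike.

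Alternatives were the Agilent log ratio, median centring without loess, no background correction, the mean over the probes of a gene, all genes tested, each comparison alone without a dye term, the swaps entered as 4 arrays, the line or the slide as a random block, array weights, the value table of the authors, each replicate or line left out, means per line and separate sets of arrays. After the data were examined, further alternatives were added: the dye term taken from the diploid swaps alone, arrays with a shifted chromosome or saturated genes left out, single slides of the Col-0 seedlings and leaves, blocks by line or replicate for differences between groups, and replicates left out of such differences. Data were handled with jsonlite 2.0.0 and version 1.17.8 of data.table, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Of the deposited data, the spot columns beyond signal, background, log ratio and quality marks were not used here.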

Results

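Gene expression in seedlings and leaves of autotetraploid and diploid Arabidopsis thaliana was compared on 48 arrays. Tetraploid and diploid RNA was compared in Col-0 seedlings on 8 arrays, in Ler-0 seedlings on 4, in Col-0 leaves on 12 and in a second set of Ler-0 plants on 8. Tetraploid seedlings of the F2 and F3 generations were compared on 4 arrays in each accession, and Ler-0 and Col-0 seedlings on 4 arrays in diploids and on 4 in tetraploids. The median spot signal of an array was 80.3 to 221.2 in Cy3 and 121.2 to 349.6 in Cy5, over a median background of 45 to 74 and 55 to 60. Between 48.4% and 65.8% of the spots in Cy3 and between 54.3% and 76.4% in Cy5 were well above background. The Cy3 medians were 80.3 to 140.7 on the leaf arrays and 113.3 to 132.5 on the diploid accession arrays, against 153.6 to 221.2 on the Col-0 seedling arrays. The number of arrays limits the precision of all values. Values are log2 ratios with their standard error (SE) from the common fit, and positive values mean more RNA in the first-named material.

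In tetraploid Col-0 seedlings the largest rise over diploids was that of MRD1 (AT1G53480), at 4.24 ± 0.21 (n = 8), or 18.9-fold, with an adjusted p of 2.6e-18. XTH26 (AT4G28850), of the xyloglucan endotransglucosylase/hydrolase family of cell wall enzymes, rose 5.64-fold, and the root potassium transporter HAK5 (AT4G13420) rose 3.23-fold. The stress regulators HSFA2 and MBF1C rose by 2.06 ± 0.46 and 1.79 ± 0.39, the early light-induced protein ELIP2 by 1.63 ± 0.34, AIG1 by 2.24 ± 0.54 and the light-harvesting protein gene LHCB2.3 by 1.99 ± 0.30. Lower in tetraploids were BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum that responds to misfolded proteins, at -2.50 ± 0.37, and the proton pump gene HA9 (AT1G80660) at -1.94 ± 0.12. SRO3 (-1.80), EXPA17 (-1.45), NAC103 (-1.40), EMB1030 (-1.39), the Argonaute gene AGO3 (-1.39) and DREB2B (-1.37) also fell. All these genes moved the same way on every array that measured them, except AIG1, which did so on 7 of 8. In the fit with the slide as a random block MRD1 had an adjusted p of 3.4e-10 and HA9 of 3.2e-08, while those of AIG1, HSFA2, MBF1C and ELIP2 became 0.14, 0.1, 0.057 and 0.068. ELIP2 was 2.70 in replicate 6 and 1.1 to 1.66 in the others.

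Genes of photosynthesis rose together in these seedlings. Of 23 list members measured, 22 rose, both over all genes tested and adjusted over the list alone, with a median of 0.94, and under all 3 other scalings the median stayed positive. CAB2 (1.47), LHCB3 (1.35) and the Rubisco small subunit gene RBCS3B (1.1) had large changes among them. The median was 0.80 on the first slide and 0.93 on the second. Against all other genes the list had an adjusted p of 1.8e-15 at the preset correlation, and an adjusted p of 0.51 with an estimated correlation. Of 14 genes of DNA methylation and silencing 1 rose and 4 fell (1 and 5 adjusted over the list alone), among them the histone methyltransferase gene SUVH4 at -0.49 and the RNA polymerase genes RDR2 at -0.44 and RDR6 at -0.36. Of the 14 genes of the DNA damage response 4 fell (4 adjusted over the list alone), with ATM at -0.33. The CDK inhibitor genes ICK1 and KRP2 rose by 0.51 and 0.37, and of their list of 10, 2 rose and 1 fell (3 and 1 adjusted over the list alone). In the cell cycle list CYCD3;3 (-0.44) and MCM5 (-0.30) fell.

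Other stress and hormone genes changed singly. In the heat shock list 4 genes rose and 4 fell (4 and 5 adjusted over the list alone), and its median of -0.15 and its mean of 0.10 differed in sign. In the salicylic acid list EDS16, which encodes isochorismate synthase, rose by 1.54 and PBS3 by 1.04, 2 of 16 measured (1 adjusted over the list alone). The iron uptake genes IRT1 (1.21), FRO2 (1.11) and BHLH101 (0.93) rose, 3 of the 12 of iron homeostasis (3 adjusted over the list alone). In the root marker list 6 genes rose and 4 fell (6 and 5 adjusted over the list alone), with EXPA18 at 0.86 and the nitrate transporter gene NRT2:1 at -0.87. SEN1 (1.47) and NAP (1.29) rose among 9 senescence genes, CCA1 (0.84) and LHY (0.80) rose and GRP7 (-0.53) fell among 12 clock genes, and 2 of 10 ethylene genes rose, with EBF2 at 0.70, with the same counts adjusted over the list alone. The medians of the CDK inhibitor, root marker and clock lists, 0.08, 0.07 and 0.03, turned to 0, -0.01 and -0.05 with median centring without loess. EXPA5 (-0.57) and EXPA4 (-0.35) fell in the cell wall list of 15 (1 adjusted over the list alone). The flowering gene AGL20 rose by 0.39 although it was -1.1 in replicate 2 and 0.15 to 1.24 in the others, and SMZ rose by 0.29 (1 of the list adjusted over the list alone). LFY rose by 0.15, with 0.71 in replicate 4 and -0.06 to 0.27 in the others, and AP3 by 0.29, both called in the list of floral organ identity and over the list alone. CPC and GL3 rose among 6 epidermis genes (2 adjusted over the list alone), and PCK1 and ABI3 fell among 14 of seed storage and maturation (2 adjusted over the list alone). In oxidative stress 1 of 18 rose and 2 fell (0 and 2 adjusted over the list alone), and in glucosinolates TGG2 rose (0 adjusted over the list alone). None of the 17 jasmonate or 18 cold and drought genes passed in limma, over all genes or adjusted over the list alone, and the adjusted p of these lists was 0.95 and 0.93.

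Over all genes, 5808 of 21844 differed, 2744 higher and 3064 lower in tetraploids, with a median size of 0.30 among them, and 194 changed at least 2-fold. The 8 arrays came from 4 lines, and the count was 2532 with the mean per line and 3650 without line 1326-26. With the slide as a random block 1358 of them passed. Median centring without loess, in place of loess, gave 2842 genes.

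Ler-0 seedlings had fewer differences between ploidies on their 4 arrays, all on 1 slide. The RNA-binding protein gene GRP2B (AT2G21060) rose by 1.31 ± 0.24 (n = 4, adjusted p = 0.0011) and BARS1 (AT4G15370), a triterpene synthase gene, by 1.04 ± 0.25. The root hair genes RHS18 (0.76), RHS13 (0.75) and RSL2 (0.75), the transcription factor gene HEC1 (0.72) and CYP708A2 (0.68) also rose. ATMPK8 rose by 0.71 on the strength of replicate 1, where it was 2.25 against 0.08 to 0.26 in the others, and without replicate 1 it was 0.19. AGP30 (AT2G33790), an arabinogalactan protein gene of roots, fell by 1.91 ± 0.23 (adjusted p = 1.2e-06), and the polygalacturonase gene PGAZAT (AT2G41850) fell by 1.82 ± 0.15, or 3.52-fold. Under the same block PGAZAT had an adjusted p of 3.2e-04, AGP30 of 0.082 and GRP2B of 0.95. GRP2B and BARS1 also rose, by 1.28 and 1.09, between F3 and F2 tetraploids, where both RNAs were tetraploid and the F3 RNA was in Cy5 as the tetraploid RNA is here.

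The genes UBQ11, UBQ3, FBA8, RCA, THI1 and RD19 were also called lower, but were at saturation in Cy5, the channel of the tetraploid RNA, on all 4 arrays. Since saturation by itself lowers such a ratio, their size, rank and direction are not known. Of the 357 genes called lower, 29 were saturated in this way, against 0 of the 276 called higher by limma, of which 276 were never saturated. Of the lists, the cold and drought list had a fall of CBF1 by 1.04 (1 adjusted over the list alone), seed storage and maturation had a rise of ICL by 0.65 and a fall of ABI3 by 0.42 (2 and 1 adjusted over the list alone), and photosynthesis had RCA and RBCS1A, both saturated. Over all genes 633 of 20939 differed. The count was 285 without replicate 1, 250 without replicate 2 and 8 with the slide as a random block. The array of replicate 4, of line 3116-6, had a chromosome 4 shift of 0.23, against 0.01 to 0.02 on the other arrays.

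On the ploidy arrays, the ploidy effect differed between seedlings of the accessions for 1162 genes. MRD1 was 3.42 lower in Ler-0, at 0.83 against 4.24 in Col-0, although Ler-0 replicate 4 alone reached 2.49 and the others 0.17 to 0.32. XTH26 differed by -2.02, HR4 by -2.05 and AGP30 by -2.50, and SRO3 by 1.81 and HA9 by 1.44, with effects of 0.01 and -0.50 in Ler-0 against -1.80 and -1.94 in Col-0. COBL2, RLP6 and EXPA17 differed by 1.2, 1.17 and 1.17, and RCA passed too, without a measured size, since it was saturated on the Ler-0 arrays. The photosynthesis list had a median difference of -0.97 with 10 called (13 adjusted over the list alone) and an adjusted p of 0.58 with an estimated correlation, but 15 of its 23 genes were saturated on at least 1 Ler-0 array. Among the other 8 the median was -0.55 and limma called 0, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The 2 effects correlated at 0.22 across 20489 genes, which are not independent replicates, against 0 in simulated unchanged groups, and 109 genes rose and 140 fell in both where 34.4 and 48.6 would be shared by independent lists. The comparison sets 1 slide against another, so slide and accession cannot be told apart, and 15 genes passed with the slide as a random block. Without Ler-0 replicate 1 or 2 the count was 651 or 698.

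**Figure D1:**
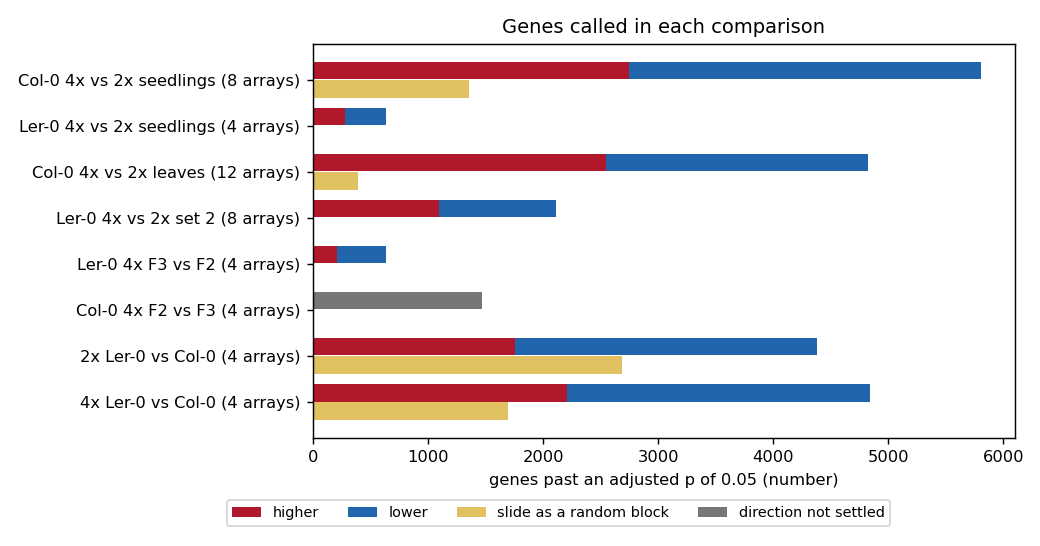
Number of genes past an adjusted p of 0.05 in each comparison (horizontal bars, all from 0), split into higher (red) and lower (blue) in the first-named material, with the count with the slide as a random block in yellow and the group without a settled direction in grey; 4x and 2x stand for tetraploid and diploid. Without the block the Col-0 seedlings have the most, 5808, and the blocked count falls to 1358 there and to 2 in the second Ler-0 set. With the block the diploid accession comparison has the most, 2683.

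In leaves of tetraploid Col-0 plants MRD1 was again the gene with the largest rise, 19.2-fold or 4.26 ± 0.27 (n = 12, adjusted p = 4.0e-14). ADS1 (AT1G06080), a desaturase gene, rose 11.9-fold, the gibberellin-regulated gene GASA6 10-fold and the expansin gene EXPA8 (AT2G40610) 9.17-fold. Auxin-related genes rose as well: IAA29 (AT4G32280) by 2.73 ± 0.32, SAUR22 by 2.62 ± 0.34 and SAUR23 by 2.33 ± 0.28, together with the growth regulator gene PRE1 by 2.3 ± 0.19. Among genes with a symbol that fell on all arrays, or all but 1, were stress and defence genes, ZAT7 at -2.57 ± 0.43, NAC090 at -2.50 ± 0.40 and the salicylic acid regulator NIMIN-2 at -1.98 ± 0.43, as well as MC8 (-2.3), LHT7 (-2.23), the cell wall gene XTH24 (-2.16) and UGT85A1 (-2.08). With the slide as a random block the adjusted p was 1.1e-06 for MRD1, 1.6e-05 for PRE1, 0.042 for ZAT7, 0.12 for LHT7 and 0.11 for NIMIN-2. ARD3 was -2.32 over all arrays but -0.15, -3.99 and -2.83 on the 3 slides.

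By list, 8 of 12 auxin genes measured in leaves rose (9 adjusted over the list alone), with a median of 1.00 that was positive under every scaling and was 1.2, 0.90 and 0.82 on the 3 slides. IAA5 (1.88) and IAA14 (1.55) were among them, and the adjusted p was 5.6e-06, or an adjusted p of 0.47 with an estimated correlation. Of 17 salicylic acid defence genes 12 fell (13 adjusted over the list alone), with a median of -1.29 that was negative under every scaling, and with NIMIN1 at -1.96 and WRKY70 at -1.85. On the 3 slides that median was -0.47, -1.83 and -1.43, and the defence gene FMO1, at -2.11 over all, was 0.05, -3.80 and -2.57. The adjusted p was 2.6e-06, or an adjusted p of 0.86 with an estimated correlation. Photosynthesis genes rose for 9 of 23 (9 adjusted over the list alone), with a median of 0.41 that was positive under every scaling, LHCA1 at 1.22 and LHCA3 at 1.01, and an adjusted p of 0.0012, or an adjusted p of 1 with an estimated correlation. In the oxidative stress list 6 of 15 genes fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.76 that was negative under every scaling. By slide, however, that median was 0.32, -1.68 and -0.95, and the first was positive under every scaling. In this list the zinc finger gene RHL41 was at -1.63 and the superoxide dismutase gene CSD2 at -1.41. The list had an adjusted p of 0.017, or an adjusted p of 0.94 with an estimated correlation.

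Single leaf genes of other lists changed too. The proline synthesis gene P5CS1 rose by 1.74, DREB1A by 1.60 and COR15B by 1.54, 3 of 5 rises in the cold and drought list (5 adjusted over the list alone), which also had 1 fall. P5CS1 was 3.11, 1.68 and 0.42 on the 3 slides. The clock genes PRR5 (1.64), GRP7 (1.34) and GI (1.3) rose, with 4 rises and 2 falls in the list (6 and 3 adjusted over the list alone). The flavonoid genes FLS1 (-1.74), F3H (-1.41) and TT4 (-1.23) fell, 3 of 8 measured (3 adjusted over the list alone), but TT4 was 0.35 on the first slide. The CDK inhibitor genes KRP2 (0.77) and LGO (0.43) rose and KRP6 (-0.75) fell (4 rises and 1 fall adjusted over the list alone). The ethylene response gene ORA59 fell by 1.37, ESM1 rose by 1.35, and the floral repressor genes SVP and FLC rose by 0.65 and 0.59. The defensin gene PDF1.2b was -3.43 over all arrays, but 1.89 on the first slide against -5.26 and -6.90 on the others. None of the heat shock or iron genes passed in limma, over all genes or adjusted over the list alone.

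Over all genes 4824 of 18926 differed in leaves, 2543 higher and 2281 lower, 542 of them at least 2-fold. With the slide as a random block 390 passed, and without line 1326-26 the count was 2050. The 12 arrays differed by slide: ratios of 2 arrays correlated across genes at a mean of 0.71 or 0.65 on the same slide, at 0.23 for other lines on another slide and at -0.08 for the same line on another slide, and genes are not independent replicates. The jasmonate and wounding list had a median of 2.39 on the first slide and of -1.45 and -1.55 on the others, the heat shock list 1.74 against -0.76 and -0.49, and the cold and drought list 1.76 against -0.21 and -0.32, each with the same sign under every scaling. With median centring without loess the median of all genes was 0.19, against 0.005 with loess, and this raised the share of called genes that were higher from 52.7% to 80%. Replicate 12 had a chromosome 2 shift of 0.16.

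**Figure D2:**
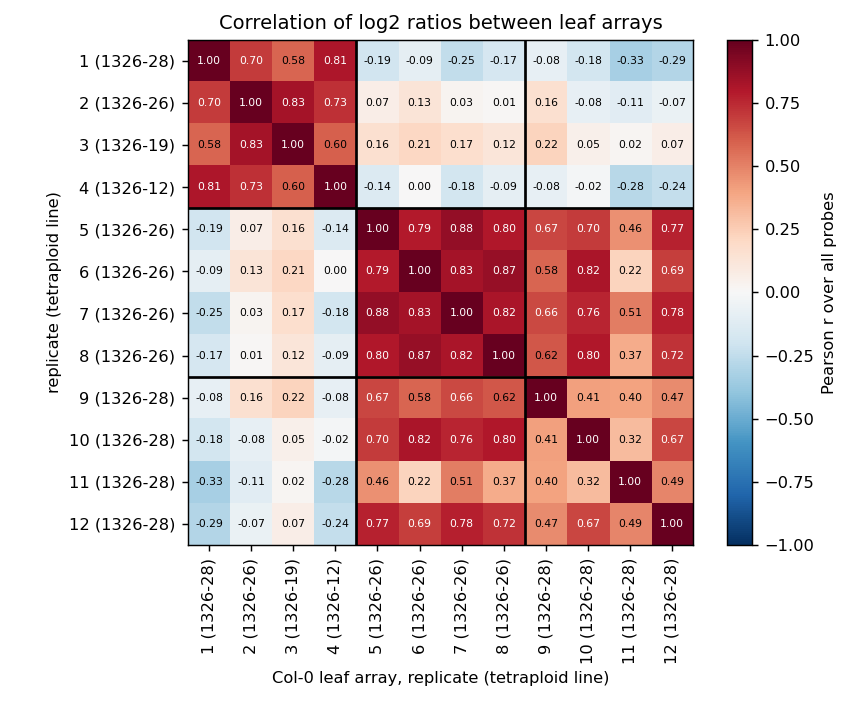
Pearson correlation over all probes between the log2 ratios of the 12 Col-0 leaf arrays (rows and columns, in replicate order with the tetraploid line). Colour runs from blue for negative to red for positive values. Black lines part the slides, which held replicates 1 to 4, 5 to 8 and 9 to 12. The highest value is 0.88, between replicates 5 and 7 on 1 slide. The lowest is -0.33, between replicates 1 and 11, of the same line on different slides.

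Leaves and seedlings of Col-0 differed in the ploidy effect at 5760 of 22064 genes, of which 454 passed with the slide as a random block. ADS1 rose in leaves by 3.57 and was -0.16 in seedlings, and EXPA8, GASA6, SAUR22 and IAA29 differed by 3.15, 2.94, 2.52 and 2.47 in the same direction. In the other direction HR4 (2.15 in seedlings, -1.67 in leaves), AIG1 (2.24 and -1.54), UGT85A1 (1.47 and -2.08), AACT1 (0.02 and -3.60) and ZAT7 (0.79 and -2.57) differed. The auxin list was higher in the leaf effect by a median of 0.87 with 7 genes called (8 adjusted over the list alone) and the salicylic acid list was lower by a median of 1.25 with 11 called (12 adjusted over the list alone), with an adjusted p of 0.58 and 0.86 with an estimated correlation. Photosynthesis genes were at a median difference of -0.36, which turned to 0.11 with median centring without loess, with 4 called (4 adjusted over the list alone) and an adjusted p of 1 with an estimated correlation. DNA methylation genes were at 0.13 with 6 called (6 adjusted over the list alone) and an adjusted p of 0.86 with an estimated correlation. The median of all genes was 0.219 with that centring, against 0.001 with loess.

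For the second Ler-0 set the sources differ on the tissue, since the sample labels say seedlings and the design text says leaves. Its signal levels correlated at 0.964 with those of the Col-0 leaf arrays and at 0.849 with the Col-0 seedling arrays across genes, which are not independent replicates, and 8 of 19 root markers were detected, as against 9 in leaves and 19 in each seedling group. GER3 (AT5G20630), a germin-like protein gene, was 24.8-fold higher in tetraploids, at 4.63 ± 0.71 (n = 8, adjusted p = 9.4e-05), and 5.37 and 3.90 on the 2 slides. PCC1 (2.09), TBL45 (1.77), ACD6 (1.65), PME5 (1.63), BZIP61 (1.57) and sks4 (1.52) also rose, and LTL1 was at least 3.26-fold higher. YLS9 (-2.19), ABCG40 (-2.17), the glutamate decarboxylase gene GAD (-1.87), CML41 (-1.87) and CAX3 (-1.74) fell. NIT2 and DREB19 fell by 1.89 and 1.87, but with -3.32 and -3.40 on the first slide and -0.45 and -0.34 on the second.

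Genes of the cell cycle rose together in this set. Of 21 measured, 16 rose (17 adjusted over the list alone) with a median of 0.69, positive under every scaling, and with slide medians of 0.67 and 0.55. SYP111 (also KNOLLE, of cell plate formation) rose by 1.19, the cyclin gene CYC1BAT by 1.06 and the mitotic kinase gene CDKB2;1 by 1.03. The list had an adjusted p of 1.3e-12, or an adjusted p of 0.58 with an estimated correlation. TSO2 (0.88) and BRCA1 (0.57), of DNA synthesis and repair, rose in their list of 14, in which 3 rose (3 adjusted over the list alone), and VIM1 (0.83) and CMT3 (0.78), of DNA methylation, as 2 of 14 (2 adjusted over the list alone), though the medians of these 2 lists, 0.08 and 0.11, turned to -0.04 and -0.07 with median centring without loess. Senescence genes had a median of -0.85, negative under every scaling, with NAP (-2.00), DIN2 (-1.69) and NAC6 (-1.63) called (4 adjusted over the list alone) and an adjusted p of 0.01, or an adjusted p of 0.86 with an estimated correlation. On the slides their median was -1.62 and -0.30, and DIN2 did not fall on the second slide. In photosynthesis 6 genes rose and 1 fell (6 and 1 adjusted over the list alone), with RBCS1B at 1.3 and LHCB2.1 at -1.47, and a median of 0.35, positive under every scaling, with an adjusted p of 0.039, or an adjusted p of 1 with an estimated correlation. The flowering promoter genes FT (-1.1) and AGL20 (-0.90) and the repressor gene MAF1 (-0.49) fell, 3 of 17 (3 adjusted over the list alone), and the ferritin gene FER1 fell by 1.62.

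Over all genes 2109 of 18597 differed, 1093 higher and 1016 lower in tetraploids, but 2 passed with the slide as a random block, and each gene named here had an adjusted p of at least 0.2 then. On the slide of replicates 1 to 4 alone 4687 genes differed, on that of replicates 5 to 8 alone 632. Without line 3116-6 the count was 932 and without line 1026-41 it was 1331. Replicates 6 and 8 had chromosome 4 shifts of 0.22 and 0.21. With median centring without loess the median of all genes was -0.144, against -0.003 with loess. Against the Col-0 leaves, the ploidy effect of this set differed at 7551 of 19407 genes, 2417 with the slide as a random block. GER3 (4.45), AACT1 (4.12) and the defensin genes PDF1.2b (3.91), PDF1.2c (3.84) and PDF1.3 (3.56) differed upwards. MRD1 (-3.89, with 0.37 in this set), GolS2 (-3.03), P5CS1 (-2.76), SIS (-2.53) and CCL (-2.52) differed downwards. The cell cycle list differed by a median of 0.46 with 16 called (16 adjusted over the list alone) and salicylic acid defence by 1.14 with 11 called (12 adjusted over the list alone). Auxin differed by -0.78 with 8 called (8 adjusted over the list alone) and cold and drought by -0.85 with 8 called (10 adjusted over the list alone). These 4 directions held under every scaling, and with an estimated correlation their adjusted p was 0.86, 1, 0.58 and 0.92. The median of all genes was -0.303 here with median centring, against -0.013 with loess, and the accession, the tissue where it is in doubt and the slides differ together.

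Between F3 and F2 tetraploid Ler-0 seedlings the largest falls were in genes for seed reserves. SESA5 (AT5G54740), an albumin gene, was at -3.08 ± 0.62 (n = 4, adjusted p = 0.0025), or 8.46-fold lower in F3, PAP85 at -2.44 and the 12S cruciferin gene CRU3 at -3.20, the last on 3 of 4 arrays. Of 19 seed storage and maturation genes 10 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -1.19, negative under every scaling, and an adjusted p of 4.2e-11, or an adjusted p of 0.47 with an estimated correlation. Without replicate 2 the value of SESA5 in Ler-0 tetraploid F3 vs F2 seedlings was -1.93 and that of PAP85 was -1.61, and without replicate 3 the gene EM1, at -2.42 over all, was -1.51. Root marker genes fell for 4 of 19 (5 adjusted over the list alone), with a median of -0.22 that was negative under every scaling, EXPA18 at -0.75, RSL4 at -0.68 and CASP1 at -0.58. This was the only list call that held with an estimated correlation, at an adjusted p of 0.029, after 1.2e-04 at the preset one.

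Other genes changed one by one between these generations. LHCB2.3 fell by 2.11 and XTH12 by 1.13, FAD8 by 1.21, NRT2.2 by 1.15 and the flavonol regulator MYB111 by 1.16, and ATPXG2 was at least 2.14-fold lower. The photosynthesis list had a median of -0.50, negative under every scaling, with an adjusted p of 2.2e-06 and an adjusted p of 0.86 with an estimated correlation, although no member passed in limma over all genes and 2 fell adjusted over the list alone. The flavonoid list had a median of -0.72, negative under every scaling, with 1 fall (2 adjusted over the list alone) and an adjusted p of 0.01, or an adjusted p of 1 with an estimated correlation. GAT1_2.1 rose by 1.76, with 2.81 in replicate 1 and 1.31 to 1.55 in the others, CYP82C2 by 1.58 and GLP6 by 1.0, while MCCB and IVD, of leucine breakdown, rose by 0.91 and 0.87. GSTU12 and BARS1 rose by 1.29 and 1.09, and without replicate 1 they were at 0.78 and 0.66. Over all genes 637 of 21426 differed, 206 higher and 431 lower, but 111 and 115 with median centring without loess and 94 and 107 with the Agilent log ratio. The count was 273 without replicate 1, 284 without replicate 3 and 1 with the slide as a random block. Replicate 4, of line 3116-6, had a chromosome 4 shift of 0.22.

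For the F2 and F3 tetraploid Col-0 seedlings the sources differ on which generation carried which dye, so only sizes are given. The cruciferin genes CRA1 and CRU3 differed by 3.11 ± 0.76 and 3.1 ± 0.66 (n = 4), and light-harvesting genes by up to 3.12 ± 0.60, the value of CAB2. LHB1B1 (2.49), LHCB2.3 (2.49), LHB1B2 (2.43), LHCB3 (1.95), LHCA1 (1.69), LHCB5 (1.56) and LHCA4 (1.47) changed in the same direction as CAB2. Of 23 photosynthesis genes 16 changed, all in 1 direction (21 adjusted over the list alone), with a median size of 0.99 that kept its side under every scaling and an adjusted p of 9.9e-18, or an adjusted p of 0.47 with an estimated correlation. Of 20 seed storage genes 10 changed in 1 direction and 1 in the other (12 and 2 adjusted over the list alone), with an adjusted p of 3.0e-06, or an adjusted p of 0.75 with an estimated correlation. The metal reductase genes FRO5 and FRO4 differed by 2.19 ± 0.13 and 2.01 ± 0.27, the nicotianamine synthase gene NAS2 by 1.64 ± 0.16, OCT1 by 1.79, NUDT4 by 1.53, CAF1a by 1.51 and NUDT24 by 1.49. Once the slide was a random block, FRO5 had an adjusted p of 1.6e-07 and NAS2 of 0.005, and 12 of the 1470 called among 21581 genes passed. The count was 709 without replicate 1 and 702 without replicate 3. FZR2 differed by 0.67, with 2.05 in replicate 1 and 0.11 to 0.28 in the others, and by 0.21 without replicate 1. In DNA methylation and silencing SUVH4 differed by 0.35 (1 adjusted over the list alone), and this list had an adjusted p of 0.027, or an adjusted p of 0.86 with an estimated correlation.

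Diploid Ler-0 and Col-0 seedlings had the largest fold differences of the series. HR4 (AT3G50480), of the RPW8 family of resistance genes, was 247-fold lower in Ler-0, at -7.95 ± 0.57 (n = 2 biological replicates), and the resistance gene RPP5 (AT4G16950) was 78.7-fold lower. LysoPL2 (-6.53), ZW9 (-6.49), the ribosomal protein gene RPS15AD (-6.39), MSR2 (-5.77), CYP89A5 (-5.62) and CYP71B37 (-5.52) were lower too. ESP (AT1G54040), the epithiospecifier protein gene of glucosinolate breakdown, was 41.1-fold higher in Ler-0 at 5.36 ± 0.39, and HO3 (3.70), CYP709B2 (3.51), UBQ13 (3.47), DES1 (3.34), CRK41 (3.34), PP2-B2 (3.01) and ESM1 (2.78) were higher too. Ratios of this kind compare hybridisation to the array probes, and their sequences were not compared with either accession here.

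Of the 7 known differences, 6 were measured and 3 were higher and 2 lower in Ler-0 (4 and 2 adjusted over the list alone). Besides ESP and ESM1, AOP3 was at least 5.92-fold higher, and the glucosinolate chain elongation gene MAM1 (-3.61) and the floral repressor gene FLC (-2.77) were lower. ER, which encodes the receptor kinase ERECTA, was at 0.63 with an adjusted p of 0.099, and AOP2 was not above background in either RNA. Among 15 flowering genes 6 fell and 1 rose (6 and 2 adjusted over the list alone), with FRI at -2.15 and MAF4 at -1.55, and among 20 glucosinolate genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). The chromomethylase gene CMT3 was at -1.22, the auxin response factor gene NPH4 at -1.87 and the glyoxylate cycle gene ICL at -1.73. In photosynthesis 3 genes rose (1 adjusted over the list alone), with a median of 0.61, positive under every scaling, and an adjusted p of 0.021, or an adjusted p of 1 with an estimated correlation. Over all genes 4381 of 21088 differed, 1759 higher and 2622 lower in Ler-0, 1514 of them at least 2-fold, and 2683 with the slide as a random block. With each of the 2 biological replicates left out, 2423 and 2469 passed, where the replicate left is assumed to vary like the other groups.

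Tetraploid seedlings of the accessions differed in many of these genes again. HR4 was 228-fold lower in Ler-0, at -7.83 ± 0.53 (n = 4), RPS15AD was at -6.45, MSR2 at -6.23, CYP89A5 at -6.09, RPP5 at -5.40, ZW9 at -5.04, emb2731 at -4.95 and PP2-A8 at -4.93. ESP was 24.8-fold higher, AOP3 at 3.18, SBT3.12 at 3.00, HAK5 at 2.72, GASA6 at 2.53 and EXPA8 at 2.40, HO3 was at least 5.84-fold higher, and LURP1 was at 3.29 with an adjusted p of 0.21 with the slide as a random block. Genes of anthocyanin synthesis were lower in tetraploid Ler-0, 9 of 14 in the flavonoid list (9 adjusted over the list alone), with a median of -1.54, negative under every scaling. DFR was at -2.94, UF3GT at -2.48 on 3 of 4 arrays and the regulator TT8 at -2.22, and the list had an adjusted p of 8.9e-04, or an adjusted p of 0.86 with an estimated correlation. FRI (-2.39), MAF5 (-1.82) and FLC (-1.43) were lower in the flowering list, with 3 rises and 4 falls (3 and 5 adjusted over the list alone).

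Of the known differences 3 were higher and 2 lower (3 and 2 adjusted over the list alone), with MAM1 at -3.59 and ESM1 at 2.11, while ER was at -0.40 with an adjusted p of 0.25 and no fold is given for AOP2, near background. In DNA methylation and silencing 6 genes fell and 1 rose (6 and 1 adjusted over the list alone), with CMT3 at -1.07, VIM1 at -0.96 and IBM1 at -0.79. VIM1 was -0.77 in replicate 2 and -1.03 to -1.01 in the others. IAA19 rose by 0.87 although it was -0.24 in replicate 4 and 1.22 to 1.26 in the others, and MLS fell by 0.90, or 0.57 without replicate 4. In photosynthesis 4 genes rose (3 adjusted over the list alone), with a median of 0.50, positive under every scaling, and an adjusted p of 0.014, or an adjusted p of 1 with an estimated correlation. Over all genes 4844 of 22128 differed, 2205 higher and 2639 lower, 1693 with the slide as a random block. The median of all genes was 0.122 with median centring without loess, against 0.008 with loess, and replicate 4 had a chromosome 4 shift of 0.21.

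The accession differences of diploids and tetraploids correlated at 0.77 across genes, which are not independent replicates, against -0.01 in simulated unchanged groups. They shared 1000 rises and 1629 falls, where independent lists would share 174 and 311.9, and 40 genes went opposite ways, against 468. The difference between them passed for 1021 of 22308 genes, 759 of them higher and 262 lower in the tetraploid than in the diploid comparison, and for 336 with the slide as a random block. LysoPL2 was at -2.48 in tetraploids against -6.53 in diploids, MAG1 at -1.34 against -4.93, CXE5 at -1.92 against -5.22, WIT2 at -0.72 against -3.96 and CML41 at 0.61 against -3.35. MRD1 was at -3.79 against -0.03, DFR at -2.94 against 0.46, UBQ13 at 0.87 against 3.47, OEP16-1 at -0.92 against 1.60 and HB4 at -0.17 against 2.3. The adjusted p of CML41 and DFR was 0.46 and 0.8 with the slide as a random block. In the flavonoid list 2 genes were called (4 adjusted over the list alone) with a median of -1.12, negative under every scaling, and the DNA methylation list had a median of -0.26, negative under every scaling. None of its members was called in limma, over all genes or adjusted over the list alone, and both lists had an adjusted p of 0.86 with an estimated correlation. Across genes the difference had a covariance of 0.006 (r = 0.04) with the difference of the ploidy effects measured directly in Ler-0 and Col-0 seedlings, against 0.017 in simulated unchanged groups, which share the dye term. Without either biological replicate of the diploid comparison the count was 549 or 565.

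**Figure D3:**
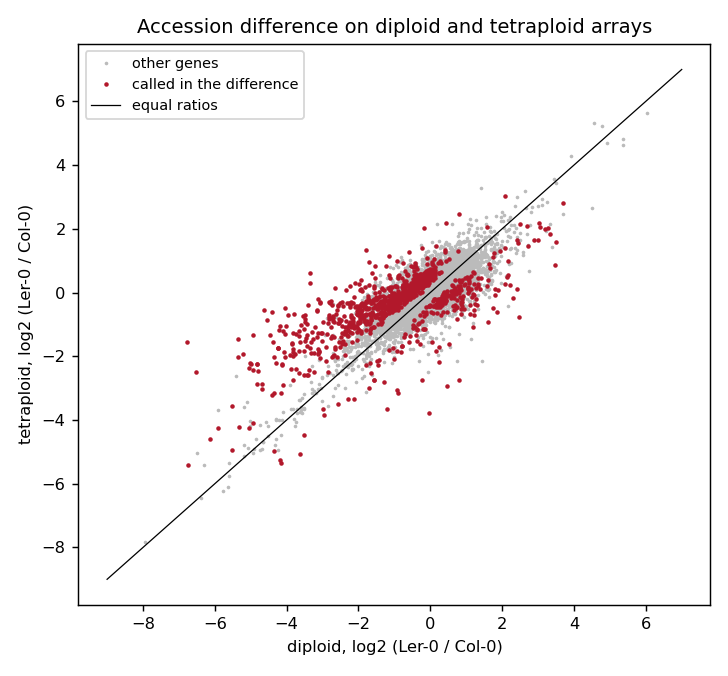
Log2 ratio of Ler-0 over Col-0 in tetraploid seedlings (vertical axis, n = 4) against that in diploid seedlings (horizontal axis, n = 2), 1 point for each of 20904 genes tested in both, with the 957 of them whose difference passed drawn in colour. LysoPL2, at -2.48 against -6.53, lies far above the diagonal line of equal values and MRD1, at -3.79 against -0.03, far below it.

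Along the chromosomes, called genes lay beside a gene called in the same direction more often than in 10000 random draws in every one of the 8 groups. In Col-0 seedlings 949 did, against a mean of 767.2 in the draws, in leaves 779 against 614.7 and in the diploid accession comparison 709 against 468.9, each with a permutation p of 1.0e-04, the smallest the draws can give. In Ler-0 seedlings, with fewer called genes, 16 did, against 9.7, with a permutation p of 0.0368. A whole-chromosome shift of at least 0.1 was found on 6 of 44 arrays. In 5 of them the genes of chromosome 4 were higher, by 0.21 to 0.23, and 4 of these carried tetraploid RNA of line 3116-6 and the other that of line 1026-40. The shift of chromosome 4 on the arrays without it had an SD of 0.012, and all shifts on the arrays without a shifted chromosome lay between -0.03 and 0.03, while those of the other chromosomes on shifted arrays were as low as -0.05, since each is taken relative to the rest. Under median centring the shifts of chromosome 4 were 0.26 to 0.28.

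**Figure D4:**
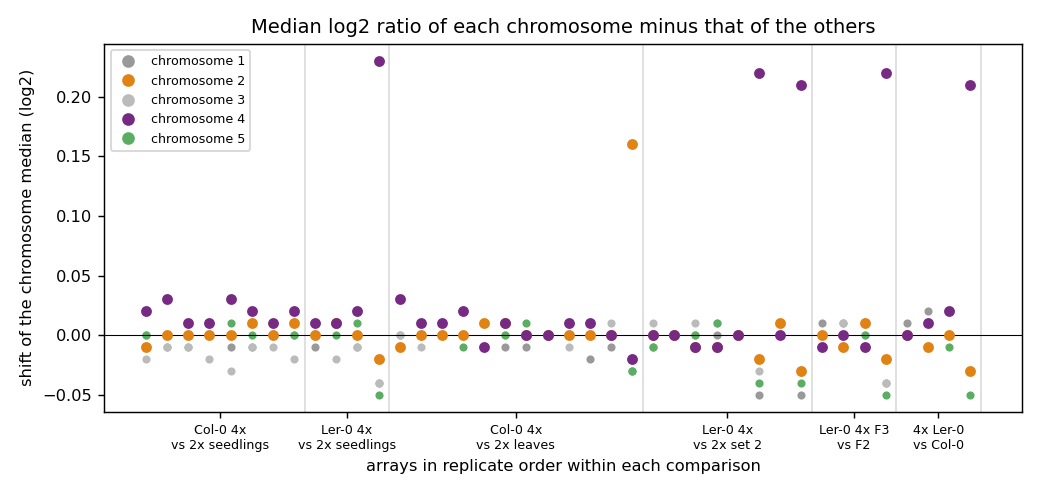
Median log2 ratio of the genes of each chromosome minus that of the other chromosomes (vertical axis), for arrays in replicate order within each comparison (horizontal axis). Each array has 1 point for each of chromosomes 1 to 5, told apart by colour, and a horizontal line marks no shift. The diploid accession arrays and the F2 and F3 comparison of Col-0 are not drawn. On 5 arrays chromosome 4 stands at 0.21 to 0.23 and on 1 array chromosome 2 stands at 0.16, while all points of the arrays without a shifted chromosome lie between -0.03 and 0.03.

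Between lines 1326-26 and 1326-28, compared in 10 leaf arrays, limma called 0 of 18928 genes, and 1073 had an unadjusted p under 0.05. Outside 1 array each on the first leaf slide, the arrays of a line were labelled as siblings and lay on a slide of that line alone. Arrays of the same line on other slides correlated at a mean of -0.08 across genes. Line and slide cannot be told apart here, so the absence of calls does not show that the lines are alike. The 4 ploidy comparisons shared 14 genes called in the same direction among 17887 tested in all. In 3 of them the tetraploid RNA was in Cy5 on every array and the dye term is shared, so the number that unchanged groups would share is not known. Of the 14 genes, 12 lay on the same side of 0 between F3 and F2 tetraploids of Ler-0, where ploidy was equal and the F3 RNA was in Cy5. GRP2B was at 1.28 there, while AT1G68810 (-0.25) and GSL10 (0.01) lay on the other side. Dye bias and ploidy are therefore not told apart for these genes. GRP2B (0.49, 1.31, 1.29 and 0.85 in Col-0 seedlings, Ler-0 seedlings, Col-0 leaves and the second Ler-0 set), TOE2 and AT1G68810 rose in all 4, and SIS3, GSL10 and AT2G32210 (-0.81, -0.75, -0.93 and -0.70) fell. The ploidy effects of seedlings and leaves of Col-0 correlated across genes, which are not independent replicates, at 0.07, against 0 in simulated unchanged groups.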

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

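The tests of intensity and of single segments for chromosome 4 were set before the result was seen, as were the splits of the arrays, whereas the other tests weighed here and the splits that follow slides were chosen only after the result was seen. Dixon's test was run on 30 sets of chromosome shifts and 222 named genes in groups of 4 to 8 arrays, of which 4 and 8 held an outlying array, and chance gives about 1 in 20.

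The genes of chromosome 4 stood out by 0.23 in replicate 4 of the Ler-0 ploidy comparison in seedlings, by 0.22 in replicate 4 of the F3 and F2 comparison of Ler-0 and by 0.21 in replicate 4 of the tetraploid accession comparison, each far from the other 3 arrays, and 2 arrays of the second Ler-0 set had the same shift. The shift was smallest at the lowest of 3 levels of signal. On the arrays with this shift it was 0.11 to 0.14 at low, 0.23 to 0.28 at middle and 0.27 to 0.29 at high signal. Its size therefore depended on signal, and the cause of this dependence was not tested. A bias limited to some levels of signal is argued against by the lowest value, 0.11. On the other arrays of these groups every level lay between -0.03 and 0.03, where the whole chromosome had an SD of 0.012 on arrays without the shift. A few strongly changed genes or one segment are argued against by the share of windows of 50 genes with a median above 0.05, at least 98.5% on each shifted array. An extra chromosome 4 in every plant of line 3116-6 is argued against by another array with tetraploid RNA of that line, replicate 4 of the second Ler-0 set, which had -0.01, and by the 0.22 between F3 and F2, where both RNAs came from that line. An extra copy of chromosome 4 in part of the tetraploid plants, for which log2(5/4) of 0.32 would be the highest value in a fully affected pool at equal output per copy, may be a cause and was not tested.

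The ploidy comparisons of Ler-0 seedlings, Col-0 leaves and the second Ler-0 set, in all of which the tetraploid RNA was in Cy5 on every array, shared 30 genes called in the same direction. Dye bias left after the dye term could explain part of them, since 86.7% lay on the same side of 0 between F3 and F2 tetraploids, where ploidy was equal and the F3 RNA was in Cy5. An error of the dye estimate from the Col-0 seedling arrays stays open, since 86.7% kept their side in all 3 comparisons with the dye term taken from the diploid swaps, which test the same dyes. Ploidy stays open as well, with 73.3% on the same side in Col-0 seedlings, which held both dye orientations, and a dye bias and a ploidy effect can add up in the same gene.

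Of the 1021 genes whose accession difference was unlike in tetraploids and diploids, 749 had the smaller difference on the tetraploid arrays. A ploidy effect that differs between Ler-0 and Col-0 is argued against by the arrays that measured it directly, where the median difference at the 749 genes, turned to the side of the accession difference, was 0.021 (95% bootstrap interval over genes -0.006 to 0.039), against a median size of 0.95 to be explained. The interval resampled genes, which share the same arrays, so it does not hold the spread between arrays or slides. Col-0 RNA mixed into the tetraploid Ler-0 samples is argued against by 69 of the 184 genes at least 8-fold lower in diploid Ler-0, whose tetraploid ratio lay more than 1 under the -1.75 that the needed share of 29.7% would give. The slide, the hybridisation or the RNA batch cannot be told apart from the groups, since each comparison lay on 1 slide, and at the 611 of the 749 genes that were lower in diploid Ler-0, the same tetraploid Ler-0 lines were 0.19 higher, relative to all genes, in the median gene on the slide of the accession arrays than on that of the ploidy arrays. Median levels of these 611 genes were 8.52 and 8.11 on these slides for tetraploid Ler-0 and 7.51 and 8.01 on the accession and ploidy slides for diploid Ler-0, with LysoPL2 at 11.12 and 8.49 and at 7.21 and 8.58. The 611 genes were picked by their ratios on the accession slides. A higher tetraploid and a lower diploid Ler-0 level on those slides therefore follows in part from the choice. Slide, hybridisation or RNA batch may be a source of the difference, and these levels do not decide it.

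Single arrays stood apart from the others of their group in the following genes. In Col-0 seedlings ELIP2 was 2.7 in replicate 6, LFY was 0.71 in replicate 4 and AGL20 was -1.1 in replicate 2. ATMPK8 was 2.25 in replicate 1 of the Ler-0 seedlings, GAT1_2.1 was 2.81 in replicate 1 of the F3 and F2 comparison of Ler-0 and FZR2 had a size of 2.05 in replicate 1 of that of Col-0. In the tetraploid accession comparison VIM1 was -0.77 in replicate 2 and IAA19 was -0.24 in replicate 4. The genes of chromosome 1 stood at -0.04 in replicate 4 of the F3 and F2 comparison of Ler-0, against 0.01 in the others.

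The ploidy effect differed between Ler-0 and Col-0 seedlings in 1162 genes by a test of the difference on the ploidy arrays. Its estimates correlated across genes at only 0.04 with those from the accession arrays. With a symbol the largest were 1.81 for SRO3, 1.44 for HA9, 1.2 for COBL2 and 1.17 for RLP6 and EXPA17. Lowest were -3.42 for MRD1, -2.5 for AGP30, -2.05 for HR4, low in Ler-0, and -2.02 for XTH26. RCA (-2.23) was saturated on all 4 Ler-0 arrays, so its size and rank are unknown. The lists of photosynthesis and of epidermis and trichomes had median differences of -0.97 and -0.41, negative under every scaling. The first had an adjusted p of 0.58 with an estimated correlation, and 15 of its genes were saturated on at least 1 Ler-0 array, while the second had 1 gene called (2 adjusted over the list alone) with an adjusted p of 0.033 at the preset correlation and an adjusted p of 0.47 with an estimated correlation.

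Leaves and seedlings of Col-0 differed in 5760 genes. With a symbol, the largest were 3.73 for ADS1, 3.15 for EXPA8, 2.94 for GASA6, 2.52 for SAUR22 and 2.47 for IAA29, and -3.83 for HR4, -3.78 for AIG1, -3.62 for AACT1, -3.55 for UGT85A1 and -3.36 for ZAT7. The lists differed by medians of 0.87 for auxin, 0.13 for DNA methylation, -0.36 for photosynthesis (0.11 with median centring without loess) and -1.25 for salicylic acid defence, and the other 3 held their sign under every scaling. With an estimated correlation the adjusted p was 0.58, 0.86, 1 and 0.86.

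The second Ler-0 set and the Col-0 leaves differed in 7551 genes. Those with a symbol were led by 4.45 for GER3, 4.12 for AACT1, 3.91 for PDF1.2b, 3.84 for PDF1.2c and 3.56 for PDF1.3, and -3.89 for MRD1, -3.03 for GolS2, -2.76 for P5CS1, -2.53 for SIS and -2.52 for CCL. The lists differed by medians of 1.14 for salicylic acid defence, 0.46 for the cell cycle, -0.78 for auxin and -0.85 for cold and drought, with the same sign under every scaling. In this order, the adjusted p was 1, 0.86, 0.58 and 0.92 with an estimated correlation. For salicylic acid defence and for cold and drought the difference depended on the leaf slide.

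The accession difference was unlike in tetraploids and diploids by 4.06 for LysoPL2, 3.95 for CML41, 3.59 for MAG1, 3.3 for CXE5 and 3.23 for WIT2, and by -3.77 for MRD1, -3.41 for DFR, -2.6 for UBQ13, -2.52 for OEP16-1 and -2.47 for HB4. The lists differed by medians of -1.12 for flavonoids and -0.26 for DNA methylation, negative under every scaling. Both had an adjusted p of 0.86 with an estimated correlation, and no member of the second was called in limma. The second had an adjusted p of 0.062 at the preset correlation with the slide as a random block.

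Probes without a locus name were outside the comparisons of genes. In Col-0 seedlings 928 of the 4164 measured passed an adjusted p of 0.05, 520 higher and 408 lower in tetraploids.

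The counts of genes were set beside those of other splits or sign patterns of the same arrays. These patterns take the arrays as independent. In Col-0 seedlings 1 of 100 sign patterns, the real one, gave as many as 5808 genes, and the highest other gave 3358. In Col-0 leaves 1 of 100 gave as many as 4824, and the highest other gave 1852. The 8 seedling arrays came from 4 lines, however. Across genes, dye-corrected ratios of the same line on the other slide correlated at a mean of 0.87, against 0.66 for other lines. Chance is therefore not excluded by these patterns in seedlings. The arrays of a slide were alike as well. Turning the sign on the slides of leaf replicates 5 to 12 together, a pattern outside the 100 of leaves, gave 4644. With the slide as a random block 390 genes passed in leaves, so chance is not excluded there. In the second Ler-0 set 2 of 100 patterns gave as many as the real 2109, the highest other 2180, a share under 0.05. This would exclude chance only if the arrays were independent, and 2 genes passed with the slide as a random block. In the 4 groups of 4 arrays the 8 sign patterns are too few for a share under 0.05, with 1 as large in each. The real and the highest other values were 633 and 0 in Ler-0 seedlings, 637 and 41 between F3 and F2 of Ler-0, 1470 and 18 between F2 and F3 of Col-0, and 4844 and 34 between tetraploids of the accessions. With 2 replicates in the diploid accession comparison, no such split was made there or for its difference from the tetraploid one.

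For the differences between groups, the arrays were again taken as independent, although arrays of a slide or line were alike. For Ler-0 against Col-0 seedlings 1 of 100 splits was as large as 1162, with 144 as the highest other. There 1 slide was set against another, and 15 genes passed with the slide as a random block, so chance is not excluded. For leaves against seedlings it was 1 of 100 as large as 5760, with 5512 as the highest other, and for the second Ler-0 set against leaves 1 of 100 as large as 7551, with 5029. Splits that follow slides gave more than the real count in 2 cases for leaves against seedlings, 9104 with the first leaf slide set with the seedling slides and 8180 with the other 2 leaf slides set with the second seedling slide, and in 2 cases for the second Ler-0 set against leaves, 8346 and 7813. With the slide as a random block 454 and 2417 genes passed in these comparisons. Between lines 1326-26 and 1326-28 limma called 0 genes, with 1073 at an unadjusted p under 0.05, so that all 100 splits gave as many by construction and decide nothing. The highest other, 2196, points to a structure of the leaf arrays.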

How the results depend on the processing

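Alternatives that took the dye term from the diploid swaps, left out arrays with a shifted chromosome or saturated genes, used single slides of the Col-0 seedlings or leaves, blocked differences by line or replicate or left out replicates of a difference were tests chosen only after the results were seen, and the others were chosen before. Of 227 values of counts, lists and shifts under an alternative, 144 stayed within 1.5 times or on the same side of the threshold, 60 became weaker, 22 stronger and 1 moved, while 0 reversed. Of 6745 values of named genes, 5544 kept their direction and side of the threshold, 1186 lost the call, 5 gained it and 10 reversed. The cause was not tested unless it is given.

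Counts are genes past an adjusted p of 0.05. With the Agilent log ratio they were 132 for ploidy in Ler-0 seedlings, 201 for F3 and F2 of Ler-0, 496 for F2 and F3 of Col-0 and 485 for Ler-0 minus Col-0. With the value table of the authors these 4 were 191, 79, 390 and 509. With median centring without loess they were 2842 in Col-0 seedlings, 271 in Ler-0 seedlings, 1253 in the second Ler-0 set, 226 for F3 and F2 of Ler-0, 875 for F2 and F3 of Col-0, 2353 and 3176 for the accessions in diploids and tetraploids, 401 for Ler-0 minus Col-0 and 536 for the accession difference between ploidies. The chromosome 4 shift of replicate 4 in Ler-0 seedlings was 0.28 with it, against 0.23. With this centring the median of all genes was 0.19 in leaves, -0.144 in the second Ler-0 set, 0.122 between tetraploid accessions, 0.219 for leaves minus seedlings and -0.303 for the second Ler-0 set minus leaves, against -0.013 to 0.008 with loess. The share of called genes that were higher went with it from 43.6% to 59% in Ler-0 seedlings, from 52.7% to 80% in leaves, from 32.3% to 49.1% for F3 and F2 of Ler-0, from 45.5% to 56.4% for tetraploid accessions, from 52% to 69.7% for leaves minus seedlings and from 48.1% to 9.2% for the second Ler-0 set minus leaves. With the Agilent log ratio it went from 51.8% to 66.8% in the second Ler-0 set and from 32.3% to 46.8% for F3 and F2 of Ler-0.

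With the arrays of each comparison alone and no dye term, the counts were 8822 in Col-0 seedlings, 7569 in leaves, 3822 in the second Ler-0 set, 3213 for F2 and F3 of Col-0, 8943 for diploid accessions, 4072 for Ler-0 minus Col-0 and 1549 for the accession difference. For F3 and F2 of Ler-0 limma then called 0 genes, with 6111 at an unadjusted p under 0.05. With the swaps entered as 4 arrays, the diploid accessions gave 7501 and the accession difference 1990, where technical copies count as replicates. Array quality weights gave 10451 in Col-0 seedlings, 3423 in Ler-0 seedlings, 9465 in leaves, 4450 in the second Ler-0 set, 3028 and 2663 for the generations of Ler-0 and Col-0, 10121 for diploid accessions, 5341 for Ler-0 minus Col-0, 10734 for leaves minus seedlings and 3855 for the accession difference.

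With the slide as a random block the counts were 1358 in Col-0 seedlings, 8 in Ler-0 seedlings, 390 in leaves, 2 in the second Ler-0 set, 1 and 12 for the generations of Ler-0 and Col-0, 2683 and 1693 for diploid and tetraploid accessions, 15 for Ler-0 minus Col-0, 454 for leaves minus seedlings, 2417 for the second Ler-0 set minus leaves and 336 for the accession difference. All these genes were also called without the block. With the dye term of the other groups from the diploid swaps, the counts were 91 in Ler-0 seedlings, 2125 in leaves, 376 in the second Ler-0 set, 169 and 704 for the generations of Ler-0 and Col-0, 7418 for diploid accessions, 446 for Ler-0 minus Col-0 and 3529 for leaves minus seedlings. Of the 30 list shifts called, 1 was called with an estimated correlation.

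With the mean per line, Col-0 seedlings gave 2532 and the second Ler-0 set 1213, from fewer samples. Without line 1326-26 the count was 3650 in Col-0 seedlings and 2050 in leaves, and in the second Ler-0 set it was 1331 without line 1026-41 and 932 without line 3116-6. All 12 Ler-0 ploidy arrays as one group gave 771 where the second set alone gave 2109. Replicates 1 to 4 and 5 to 8 alone gave 4687 and 632 in the second Ler-0 set, and replicates 5 to 8 of the leaves gave 8772. In Col-0 seedlings they gave 909 and 809, with the dye term taken from the diploid swaps as well. The leave-one-out counts were 250 to 654 in Ler-0 seedlings, 273 to 775 and 702 to 1514 for the generations of Ler-0 and Col-0, 3964 to 4782 and 2423 to 2469 for tetraploid and diploid accessions, 651 to 1133 for Ler-0 minus Col-0 and 549 to 1186 for the accession difference. The low values were without replicate 2 in Ler-0 seedlings, without replicate 1 and 3 for the generations of Ler-0 and Col-0, and without Ler-0 replicate 1 and diploid replicate 1 in the differences.

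No background correction, the mean over the probes of a gene, all genes tested and the line as a random block left all counts within 1.5 times, and so did leaving out shifted arrays or, with 585 in Ler-0 seedlings, saturated genes. Named genes reversed with median centring without loess were ABI5 at -0.26 and TGG2 at 0.33 in leaves and SAG12 at 0.06 between F3 and F2 of Ler-0. In replicates 5 to 8 of the second Ler-0 set DIN2 was 0.02. In replicates 1 to 4 of the leaves KU70 was 0.11, FMO1 0.05, GSTU24 0.35, TT4 0.35 and PDF1.2b 1.89, the last with an adjusted p of 0.0047, and in replicates 9 to 12 SAG21 was 0.03. Signal over background was low in leaves, with Cy3 medians of 80.3 to 140.7 over a background of 46 to 48, and in the second Ler-0 set, with a background of 52 to 74, and 18926 and 18597 genes were tested there against at least 20939 in the seedling groups.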

Other observations

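The list medians by slide, the loci of organelles and the values of single lines in this part came from tests chosen only after the results were seen.

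The leaves of tetraploid and diploid Col-0 plants differed in opposite ways on different slides. On the first slide, with 1 array for each of 4 lines, stress lists were higher in tetraploids: the medians were 2.39 for jasmonate and wounding, 1.76 for cold and drought, 1.74 for heat shock, 1.2 for glucosinolates and 0.58 for senescence. On the other 2 slides, with 4 arrays of line 1326-26 and 4 of line 1326-28, they were lower, at -1.45 and -1.55, -0.21 and -0.32, -0.76 and -0.49, -0.3 and -0.69, and -0.91 and -0.96, each with the same sign under every scaling. Salicylic acid genes were lower on all 3, at -0.47, -1.83 and -1.43, and auxin genes higher, at 1.2, 0.9 and 0.82, with the same signs under every scaling. Arrays of the same line on different slides correlated at a mean of -0.08 across genes, which are not independent replicates. Line, plant batch and slide were not tested apart, and no explanation was tested.

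Mitochondrial genes, and loci of chromosome 2 in the region of its nuclear insertion of mitochondrial DNA, were lower in tetraploid Col-0 seedlings under every scaling. Whether probes of these nuclear loci also read mitochondrial RNA was not tested, so they may not be a separate result. Of 4 mitochondrial loci measured, 3 fell, also with the slide as a random block, with a median of -0.93. On chromosome 2, of 52 measured loci between AT2G07630 and AT2G07787, 38 fell with a median of -0.41, and 16 fell with the slide as a random block. These loci were picked after their values were seen, in a scan along the chromosomes. In Ler-0 seedlings 2 of 49 of them rose and 1 fell, in leaves 8 of 47 fell, in the second Ler-0 set 1 of 49 rose and 4 fell, and between tetraploid accessions 1 of 52 rose and 13 fell.

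MRD1 was 4.24 higher in tetraploid than in diploid Col-0 seedlings and 4.26 higher in leaves, while it was 0.83 in Ler-0 seedlings and 0.37 in the second Ler-0 set. Between tetraploids of the accessions it was at -3.79 in Ler-0 over Col-0, and between diploids at -0.03. In replicate 4, of line 3116-6, it was 2.49 in the Ler-0 ploidy comparison, against 0.17 to 0.32 in the others, and the same line had -1.96 in the tetraploid accession comparison.

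Probes without a locus name passed an adjusted p of 0.05 in 76 cases in Ler-0 seedlings, 455 in leaves, 62 in the second Ler-0 set, 64 and 197 between generations of Ler-0 and Col-0, and 395 and 814 between diploid and tetraploid accessions. Where at least 2 probes of a locus were called, all its tested probes, called or not, had the same sign at 59 of 64 loci in Col-0 seedlings. The same held at 53 of 55 in leaves, 48 of 60 between diploid accessions and 44 of 55 between tetraploid ones. The gene dye terms of the Col-0 seedlings and of the diploid swaps correlated at 0.57 across 20763 genes, which are not independent replicates.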
